A study of Lepeophtheirus salmonis with 11 samples.

How the data were processed

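The series measured RNA of pooled adult salmon lice on 11 two-colour oligonucleotide arrays, 7 with pools from fish on a control diet and 4 with pools from fish on a low dose immunostimulant diet. Per the labels, 825 ng of total RNA per sample was used, the sample was labelled with Cy5 on every array, and the Cy3 channel held a common reference made from all conditions. No array had the dyes exchanged.

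The deposited scanner files, 22 in all, hold 1 dye channel of 1 array each, and their values are spot intensity from ImaGene 8.0.1, not normalised, per the file headers. Each array has 45220 spots, of which 38132 are probes and 7088 are control or unused spots. The authors also deposited a table of lowess normalised log2 ratios (Cy5 over Cy3) for 19965 probes, and the deposited series matrix holds the same log2 values, with a largest difference of 0. The processing notes name limma, without a version and without saying what it was used for. How the authors corrected background, handled spot flags and came to 19965 probes is not given. The authors' values correlated with the log2 ratio of the raw intensities at 0.933 or more on every array (across probes, which are not independent replicates), and with the values used here at 0.96 or more.

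The comparisons were computed from the scanner files with limma 3.58.1 in R 4.3.3. Background (the local background median) was corrected by the normexp method with an offset of 50, and each array was normalised by loess with a span of 0.3. Control spots and unsaturated spots with a poor flag had weight 0. These unsaturated flagged spots, 1.39% of probe spots, were set to missing and are the poor spots named below. Spots with a poor flag that were saturated in either channel were kept, an exception that the rule fixed beforehand did not hold. Removal could thus differ between groups where only 1 of them was saturated. The poor spots were concentrated among bright spots, with spots ranked by Cy5 signal into 10 equal bins. They made up 9.1% of the brightest bin, 2.08% of the next and at most 0.567% of each of the other 8. Saturated spots, 3.11% of probe spots, were kept, and the size of a difference with saturated Cy5 signal was taken as uncertain. A probe was kept if its Cy5 signal exceeded the local background median by over 2 background SDs on at least 4 arrays, which left 26002 probes. Of these, 12595 had a description in the authors' table and 13407 had none, and the descriptions gave 4405 distinct names. The names are the authors' similarity descriptions and were not checked against the louse genome: the gene table at hand could not be joined to the probes, so no coordinates are given.

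The values are log2 ratios of sample over reference. Differences are low dose minus control, or sampling time 4 minus sampling time 3. Each probe was tested by limma's moderated test, two-sided, with the Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. A looser count took probes at an unadjusted p under 0.01 and at least 1.5-fold. The diet comparison used all 11 arrays with no covariate. The labels mark sampling time as not used, so time was compared within the 7 control pools. No paired analysis was possible because the groups share no replicate numbers. Slide was not a term of the fit, since only 2 of the 5 slides held both diets.

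Fixed before the data were examined were the comparisons, the filter, 19 gene lists defined by words in the descriptions, the rule for the genes named, and most of the alternatives. The lists were tested by camera with a preset correlation of 0.01, adjusted over the 18 lists with at least 5 names. The yolk and eggshell list had 3 names and was not tested. Membership rests on words in the descriptions alone, so a member need not have the function its list is named after. Camera with an estimated correlation, fry, and an exact two-sided permutation of the arrays on each list's mean log2 ratio per array were run beside it. The genes named in each direction were to be the 10 with the largest change past the adjusted threshold, filled up, where fewer passed, with the probes of smallest unadjusted p at 1.5-fold or more, 1 probe per name. The 2 members of each list with the smallest p were added, as was the undescribed probe with the smallest p in each direction.

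The alternatives fixed beforehand were no background correction, an offset of 16, median centring, quantile normalisation of average intensity, no filter, a filter on all 11 arrays, the authors' table, the series matrix, slide as a fixed or random block, sampling time as a covariate, sampling time 4 alone, pools of 2 lice alone, array weights, a trended and robust variance model, 1 value per name, and leaving out each array. Chosen after seeing the data were leaving out control pools 6 and 18, leaving out these and low dose pool 15, the cell cycle list mean as a covariate, keeping poor spots, matching the lists on whole descriptions, and the permutation of list means.

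The fit was tested on simulated data with the groups' sizes and spread. In the diet design, 12% of 50 probes changed by 1.5-fold were recovered, 42% of those changed by 2-fold and 84% of those changed by 4-fold, with 5 of 23310 unchanged probes called. In the time design, recovery was 0%, 4% and 58% at the same folds, with 5 of 23782 unchanged probes called. The noise was simulated as independent between pools, with no pools standing apart, so recovery on the real arrays may differ. In both designs, camera called the shifted list and 0 of the 17 other lists, but the probes were simulated as independent, so this does not measure false list calls on the real arrays. There the estimated correlation within a list reached 0.62, and the other splits of the arrays gave a median of 7 lists called for diet and 6 for time. Precision is limited by the number of arrays: the median SE of a log2 difference was 0.24 for diet and 0.30 for time.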

Results

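Adult salmon lice (Lepeophtheirus salmonis), blood-feeding copepod parasites of salmon skin, were collected from Atlantic salmon that had been fed a control diet or a diet with a low dose of an immunostimulant. The lice came from a region with raised resistance to emamectin benzoate, an avermectin used to treat infested fish. Feeding began 17 days before the first sampling, and fish were exposed to lice again on days 14 and 28. Each pool held equal numbers of males and females from the same fish and was measured on its own array. The control diet group had 7 pools, 4 from sampling time 3 (day 40 after first exposure) and 3 from sampling time 4 (day 47). The low dose group had 4 pools, 1 from sampling time 3 and 3 from sampling time 4. All 7 control pools and low dose pools 14 and 15 held 2 lice, and low dose pools 11 and 19 held 4. On each array, 63.4% to 70.9% of the probes were above background in the sample channel, and the number of arrays limits the precision. The reference channel correlated at 0.995 or more between every pair of arrays, and the sample channel at 0.877 or more (across probes).

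Control pools 6 and 18 and low dose pool 15 stood apart from the rest. Across 23647 probes measured on every array, the first principal component held 47.7% of the variance and separated control pools 6 and 18 from the other 9 pools, and the second held 15.6% and separated low dose pool 15. The correlation of log2 ratios between 2 pools, across probes, ranged from -0.43 (control pools 6 and 10) to 0.81 (control pool 7 and low dose pool 14). The labels state the dyes of every array, so the direction of each array was kept as labelled. The mean log2 ratio of the cell cycle and DNA replication list was -1.15 in control pool 6 and -0.85 in control pool 18, against -0.20 to 0.13 in the other 9. Control pools 6 and 18 also had the highest means of the muscle list, 0.50 and 0.35, and of the protease inhibitor list, 0.89 and 0.85. Low dose pool 15 had the lowest mean of the protease inhibitor list, -1.74.

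**Figure D1:**
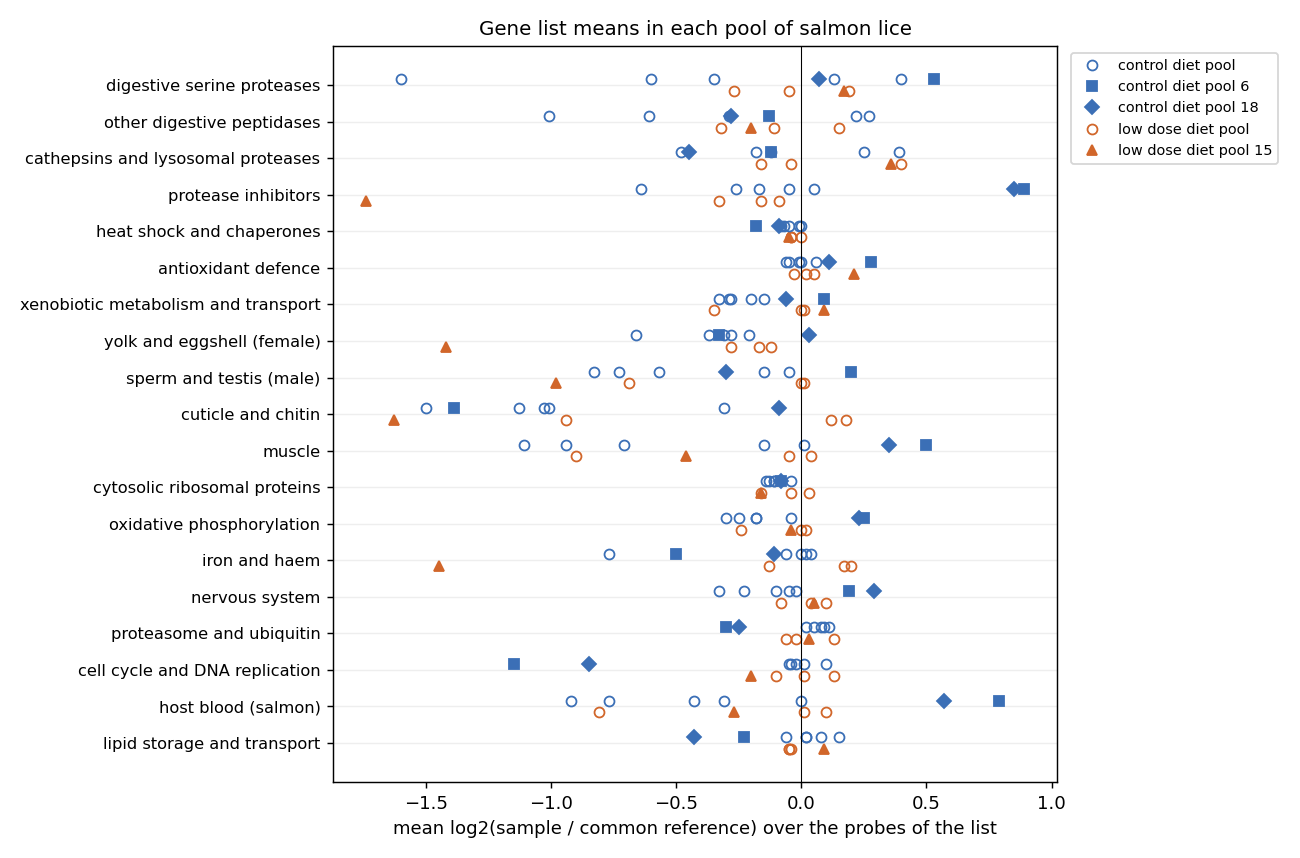
Mean log2 ratio of sample over common reference for the probes of each of the 19 gene lists (horizontal axis), 1 symbol per pool, with control diet pools in blue and low dose pools in orange. Control pools 6 and 18 (filled square and diamond) lie at -1.15 and -0.85 in the cell cycle list, and low dose pool 15 (filled triangle) lies at -1.74 in the protease inhibitor list.

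The first comparison asked whether lice from fish on the low dose diet differed from lice on control fish. Dehydrogenase/reductase SDR family member 1, a short-chain oxidoreductase, had a log2 ratio of -0.31 ± 0.08 (SD, n = 4) in low dose pools and 0.73 ± 0.48 (SD, n = 7) in control pools, and all 4 low dose pools (-0.41 to -0.22) lay below all control pools (0.34 to 1.74), while 7 of the 10 probes of this name were lower. This probe was chosen by its small p among 25914 tested, so the separation of its pools is no further support. NADPH oxidase 5, an enzyme that makes superoxide, had -0.32 ± 0.17 (SD, n = 4) against 0.44 ± 0.44 (SD, n = 7). Granulin-7, named after a family of secreted growth factors, had 0.37 ± 0.19 (SD, n = 4) against -0.40 ± 0.42 (SD, n = 7), and all 8 of its probes were higher in low dose pools. Slides 1 and 3 were the slides with both diets, and the control pools of slide 3 were pools 17 and 18. Within slides 1 and 3, the 3 genes differed by -0.86 and -0.78, by -0.06 and -1.06, and by 1.06 and 0.92. None of these differences, and no other probe, passed the adjusted threshold.

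By limma, 0 of 25914 probes passed at an adjusted p under 0.05, and the smallest adjusted p was 1. At an unadjusted p under 0.05 there were 363 probes, where 1296 would be expected with no difference. The looser count held 31 probes, 20 higher and 11 lower in low dose pools, of which 7 had a description. For scale, 47 probes had an unadjusted p under 0.01, where 259 would be expected. Counts this far below the expected ones are no evidence that the diet had no effect, since p-values may not spread evenly where pools stand apart. The looser count was 205 without control pools 6 and 18, 50 without control pool 18 alone and 81 in sampling time 4 alone.

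Of the other named probes with higher values in low dose pools, the log2 difference was 1.09 (SE 0.33) for ribosomal protein P2 of the large subunit stalk, 1.80 (SE 0.64) for Prolyl 4-hydroxylase subunit alpha-2, a collagen-modifying enzyme, and 1.17 (SE 0.46) for Cytochrome b of respiratory complex III. It was 2.15 (SE 0.84) for a carboxylesterase and 2.15 (SE 0.85) for Neuroligin-4, Y-linked, which belongs to a family of esterase-like adhesion proteins. These 2 probes had near-equal differences within slide 1 (3.86 and 3.84) and slide 3 (1.05 and 1.04), so they may not be separate findings. Cellular retinoic acid-binding protein 2 differed by 0.90 (SE 0.28), B-cell receptor-associated protein 31 by 0.70 (SE 0.25) and Pyrazinamidase/nicotinamidase by 0.62 (SE 0.21). For the latter only 1 of 3 probes was higher, and for the carboxylesterase 2 of 4. A type IV collagenase, which is a matrix metalloproteinase, differed by 2.77 (SE 0.48), but on 1 low dose and 2 control pools alone, and by 1.24 with poor spots kept.

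Of the named probes with lower values in low dose pools, Zinc metalloproteinase nas-6 and nas-14, astacin-like proteases, differed by -3.56 (SE 1.24) and -2.97 (SE 1.12), with SDs of 1.78 to 2.38 between pools of a diet. Within slides 1 and 3, nas-6 differed by -4.09 and -1.88 and nas-14 by -3.63 and -1.85, so these too may not be separate findings. The nas-6 probe was saturated on 1 control array, and nas-14 was above background in 2 of the 4 low dose pools. Phospholipase A2 differed by -1.78 (SE 0.66) but was above background in 1 of the 4 low dose pools, so the size of its difference is uncertain. L-amino-acid oxidase differed by -1.81 (SE 0.60) and Histone H2B by -1.33 (SE 0.48), the last with 6 of 10 probes lower. Histone H2B was -2.29 with slide as a block, -0.88 without low dose pool 11 and -0.41 with pools of 2 lice alone. Muscle M-line assembly protein unc-89 differed by -0.74 (SE 0.27, 4 of 6 probes lower), Ran-binding protein 3 by -0.61 (SE 0.22, 1 of 2 probes lower) and Neuroglian, a neural adhesion protein, by -0.60 (SE 0.22, and by -0.39 without low dose pool 14). Among probes with no description, number 12687 differed by 1.17 (SE 0.26) and was above background in 1 of the 7 control pools. Number 12448 differed by -2.58 (SE 0.51) and was above background in 1 of the 4 low dose pools. The 20 named probes were chosen by their small p on these same arrays, so a kept sign in a refit was likely beforehand and is no support. With slide as a block, 18 of the 20 named differences could be estimated and all 18 had the same sign, though Pyrazinamidase/nicotinamidase fell to 0.27, Neuroglian to -0.20 and unc-89 to -0.18. Those estimates compare low dose pools 11 and 19, the pools of 4 lice, with control pools of the same slides, among them control pool 18. With 1 value per name, the mean of its probes, Dehydrogenase/reductase SDR family member 1 was -0.43, NADPH oxidase 5 -0.48, the carboxylesterase 0.73, Pyrazinamidase/nicotinamidase 0.09, Histone H2B -0.28 and Ran-binding protein 3 -0.12.

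**Figure D2:**
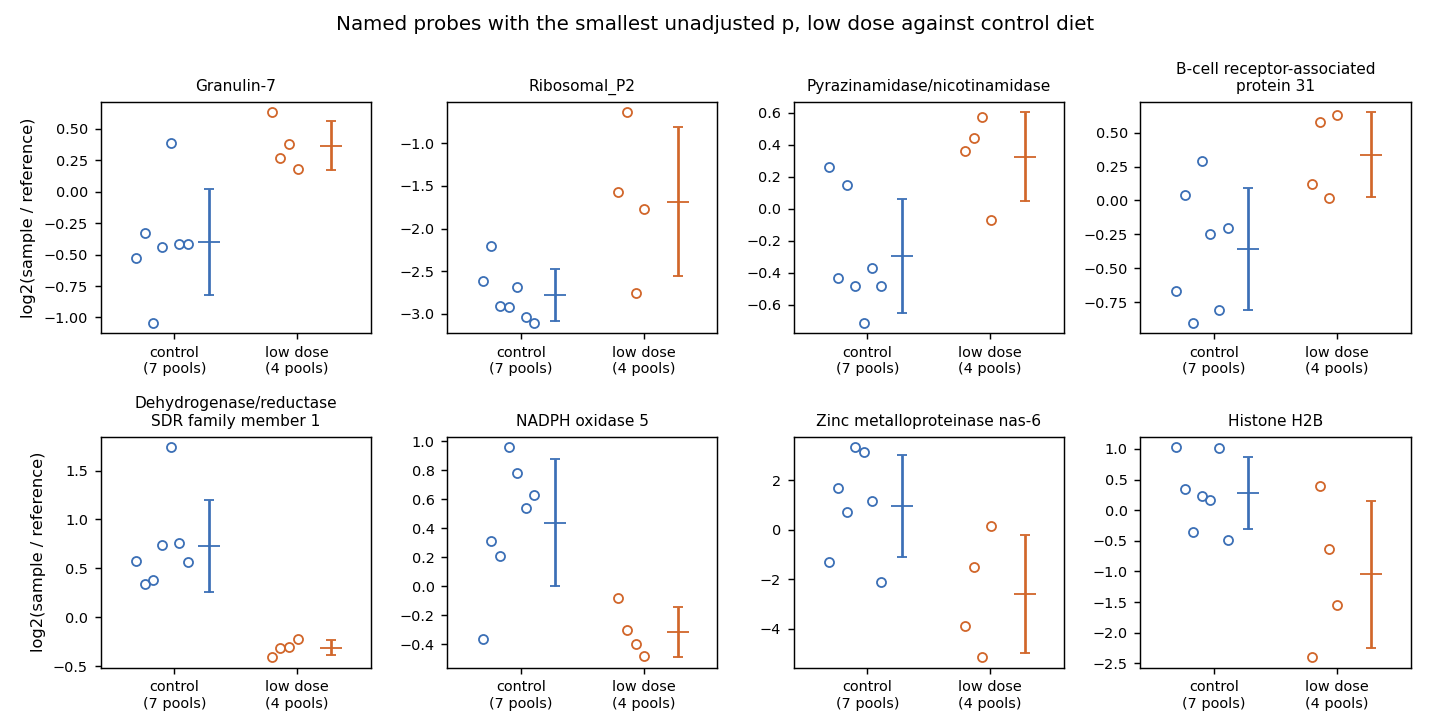
Log2 ratio of sample over reference (vertical axis, scaled per panel) in each pool for the 4 named probes with the smallest unadjusted p in each direction among those measured on all 11 arrays, with control diet pools in blue and low dose pools in orange. Bars give the mean and SD; the 4 low dose pools lie below the 7 control pools for Dehydrogenase/reductase SDR family member 1 (-0.41 to -0.22 against 0.34 to 1.74), and the other panels overlap.

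By camera with the preset correlation, 3 of the 18 lists tested passed for diet, and 0 passed with an estimated correlation, by fry or by exact permutation (5 lists passed by camera without control pool 7). The smallest possible exact permutation p was 0.003, so after adjustment over the 18 lists a single list could not pass by permutation. In no list did a probe pass, adjusted over all probes or adjusted over the list alone. The protease inhibitor list, which holds serpins and Kunitz-type inhibitors, fell: 56 of 83 probes were lower, with a median log2 difference of -0.21 and a mean of -0.68 (camera adjusted p = 2.12e-08). Leaving out single pools moved the median from -0.40 (without control pool 7) to -0.15 (without control pool 6). With an estimated correlation the adjusted p = 0.948, and list means were -0.58 ± 0.78 (SD, n = 4) against 0.10 ± 0.57 (SD, n = 7), exact permutation p = 0.155. Tissue factor pathway inhibitor differed by -3.09 (SE 1.32, 3 low dose pools) and Papilin by -2.29 (SE 1.00), neither past the threshold, and Tissue factor pathway inhibitor was saturated on 3 control arrays. Without low dose pool 15 they differed by -0.88 and -1.13, with slide as a block by -0.075 and -0.86, and with poor spots kept Tissue factor pathway inhibitor differed by -2.49. All 4 low dose pools lay below the control mean, where pool 15 had -1.74 and control pools 6 and 18 had 0.89 and 0.85. Without control pools 6 and 18 the median was -0.14 (camera adjusted p = 0.404). With slide as a block it was -0.07 (camera adjusted p = 0.269), and within slides 1 and 3 the list means differed by 0.19 and -0.54. On slide 3 the list mean was -0.09 in low dose pool 19, 0.05 in control pool 17 and 0.85 in control pool 18.

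The cuticle and chitin list, of exoskeleton proteins, rose by the same test: 61 of 76 probes were higher, with a median of 0.27 (camera adjusted p = 0.00243, adjusted p = 0.948 with an estimated correlation). Cuticle protein 6 differed by 1.25 (SE 0.60, by 0.59 with poor spots kept and by 0.73 without control pool 12) and an insect cuticle protein with a chitin-binding domain by 1.29 (SE 0.70). List means were -0.57 ± 0.88 (SD, n = 4) against -0.92 ± 0.53 (SD, n = 7), exact permutation p = 0.388. The pools of 4 lice, low dose pools 11 and 19, had 0.12 and 0.18, and low dose pools 14 and 15 had -0.94 and -1.63, inside or below the range of control pools (-1.5 to -0.09). With pools of 2 lice alone the median was -0.27, in the opposite direction (camera adjusted p = 0.0158). The call was lost without low dose pool 11 (median 0.12), low dose pool 19 (0.09) or control pool 12 (0.18), and the median was 0.57 at most without single pools. With slide as a block the median was 0.91 (camera adjusted p = 6.65e-16), and within slides 1 and 3 the list means differed by 1.39 and 0.72, each time between a pool of 4 lice and pools of 2.

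The cell cycle and DNA replication list rose: 103 of 122 probes were higher, with a median of 0.17 (camera adjusted p = 0.00243, adjusted p = 0.948 with an estimated correlation). List means were -0.04 ± 0.14 (SD, n = 4) against -0.29 ± 0.50 (SD, n = 7), exact permutation p = 0.4. Its members with the smallest p were DNA polymerase epsilon subunit 2, at 0.33 (SE 0.17), and a chromosome segregation ATPase, at -0.21 (SE 0.11). The former was 0.21 without low dose pool 14 and 0.07 with slide as a block, and 0.02 and 0.11 within slides 1 and 3. Without control pools 6 and 18, which had the lowest means, the median turned to -0.08 (camera adjusted p = 0.00355). The call was lost without control pool 6 (median 0.08), control pool 18 (0.14) or low dose pool 14 (0.13), and the median was 0.26 at most without single pools. With slide as a block the median was 0.03 (camera adjusted p = 0.871), and within slides 1 and 3 the list means differed by -0.02 and 0.35. On slide 3 the list mean was -0.1 in low dose pool 19, -0.05 in control pool 17 and -0.85 in control pool 18.

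The other 15 lists tested did not pass for diet (camera adjusted p from 0.14 to 0.941). Among lists of digestion, the median log2 difference was 0.21 for digestive serine proteases, 0.15 for other digestive peptidases and 0.10 for cathepsins and lysosomal proteases. The cathepsin list passed as higher without control pool 7 (median 0.14), control pool 12 (0.15), low dose pool 11 (0.17) or low dose pool 19 (0.16), and the serine protease list without control pool 6 (0.28) or without both control pools 6 and 18 (0.33). However, the cathepsin median was 0.01 without control pools 6 and 18 (camera adjusted p = 0.957) and 0.07 with slide as a block (camera adjusted p = 0.738). Within slides 1 and 3 the cathepsin list means differed by -0.15 and 0.31. The serine protease median ranged from 0.12 to 0.31 without single pools. Chymotrypsin-like protease CTRL-1 differed by -1.54 (SE 0.60), a trypsin-like serine protease by -1.81 (SE 0.81), Gamma-interferon-inducible lysosomal thiol reductase by 0.66 (SE 0.48) and Lysosomal-trafficking regulator by 0.44 (SE 0.37). The first 2 were -1.01 and -1.16 without control pools 6 and 18, and Lysosomal-trafficking regulator was 0.01. The trypsin-like protease was -1.01 without low dose pool 15 and -0.92 with slide as a block, and the thiol reductase was 0.41 without control pool 17 and 0.41 with slide as a block. Among lists of stress and detoxification, the median was 0.04 for heat shock and chaperones, 0.01 for antioxidant defence and 0.06 for xenobiotic metabolism and transport. The chaperone CBP3 homolog of complex III differed by 0.44 (SE 0.16), Proteasome assembly chaperone 2 by 0.32 (SE 0.13), Peroxiredoxin-2 by 0.44 (SE 0.27, saturated on 1 low dose array), Thioredoxin-like protein 4A by 0.28 (SE 0.14) and Heparan sulfate 2-O-sulfotransferase pipe by 1.15 (SE 0.47). The last 2 entered their lists by a word in the name, and a role in stress or detoxification was not checked. The median was -0.03 for oxidative phosphorylation, where Cytochrome c oxidase subunit 2 differed by 1.23 (SE 0.49), 0.02 for proteasome and ubiquitin, where 26S proteasome non-ATPase regulatory subunit 10 differed by 0.29 (SE 0.11, and by 0.05 to 0.32 over the alternatives), and 0.01 for cytosolic ribosomal proteins, where 60S ribosomal protein L10a differed by -0.35 (SE 0.18) and 40S ribosomal protein SA by -0.27 (SE 0.15). L10a was -0.14, SA was -0.18 and Proteasome assembly chaperone 2 was 0.17 with slide as a block. The proteasome and ubiquitin list passed as lower with slide as a block (median -0.03, camera adjusted p = 0.00501) and without control pools 6 and 18 (-0.06, camera adjusted p = 0.00327), where oxidative phosphorylation passed as higher (0.10, camera adjusted p = 0.000185) and Peroxiredoxin-2 was 0.20.

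Among lists of other tissues, the sexes and the host, the median for diet was -0.03 for muscle, 0.03 for nervous system, -0.04 for sperm and testis and -0.05 for host blood. The muscle list passed as lower without control pool 7 (median -0.16), 10 (-0.10) or 12 (-0.18) or low dose pool 11 (-0.12) or 19 (-0.14), and as higher without control pools 6 and 18 (0.24) or with slide as a block (0.42). The nervous system and host blood lists also passed as higher without control pools 6 and 18 (medians 0.16 and 0.24). Myosin heavy chain 95F, which entered the muscle list by the word myosin, differed by -0.41 (SE 0.16, and by -0.51 to -0.06 over the alternatives). The transporters NTT73 and Sodium- and chloride-dependent GABA transporter 1 differed by -0.44 (SE 0.35) and -0.41 (SE 0.35), and Dynein heavy chain 6, axonemal by -0.52 (SE 0.17). Spermine oxidase, which entered the sperm list by its spelling, differed by -0.41 (SE 0.18), by -0.22 without low dose pool 14 and by -0.16 with slide as a block, and within slides 1 and 3 by -0.48 and 0.17. Dynein heavy chain 6 was -0.34 and GABA transporter 1 was -0.03 with slide as a block, and without control pool 18 NTT73 was -0.20. Whether any probe of the host blood list reads salmon RNA was not tested. The list held immunoglobulin-domain proteins that arthropods also make: its members with the smallest p, an I-set domain protein and Leucine-rich repeats and immunoglobulin-like domains protein 1, differed by -0.19 (SE 0.25) and -0.21 (SE 0.47). These were 0.06 and 0.16 without control pools 6 and 18, and both transporters were then at -0.09. The median was 0.08 for iron and haem, where an animal haem peroxidase differed by 1.5 (SE 1.24) and a large exoprotein of the FhaB family by -2.18 (SE 1.38). However, the peroxidase was at 0.80 without control pool 18 and at -0.04 without control pools 6 and 18, and the exoprotein, saturated on 2 control arrays, was at -0.46 without low dose pool 15 and at -0.61 with slide as a block. It was 0.00 for lipid storage and transport, where Acyl-CoA dehydrogenase family member 9 differed by 0.38 (SE 0.20) and Acyl-CoA synthetase family member 2 by -0.24 (SE 0.15), and by 0.19 and -0.44 with slide as a block. The yolk and eggshell list was not tested and had a median of -0.05. Camera gave the opposite sign to the median for antioxidant defence, cytosolic ribosomal proteins, iron and haem, nervous system, proteasome and ubiquitin, and lipid storage and transport, and the mean of oxidative phosphorylation, 0.01, differed in sign from its median.

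The second comparison asked how control diet pools of sampling time 4 differed from those of sampling time 3, a week earlier. Muscle genes were lower on average at sampling time 4: of the 301 muscle probes, 277 were lower, with a median log2 difference of -0.74 (camera adjusted p = 1.40e-20, adjusted p = 0.686 with an estimated correlation). The time 3 control pools 6 and 18 had the highest muscle means, and without them the median was -0.25 (camera adjusted p = 4.95e-05). The mean was 0.01 in the highest pool of time 4 and -0.71 in the lowest of time 3, and 2 of the 3 pools of time 4 lay below the mean of time 3. Leaving out single pools moved the median from -1.14 (without control pool 3) to -0.47 (without control pool 12). Myosin heavy chain, muscle, the motor of the thick filament, had -1.01 ± 0.63 (SD, n = 3) at time 4 and 0.52 ± 0.42 (SD, n = 3) at time 3, with 68 of its 69 probes lower. Troponin I, of the thin filament, was lower on all 16 probes and differed by -1.64 (SE 0.34), on 2 pools per time, and was saturated on 2 time 3 arrays. The time 3 pools behind this difference were control pools 6 and 18 alone, so it shows no fall apart from these pools. Genes of lysosomes were higher at time 4, with 40 of 47 probes of the cathepsin and lysosomal list above time 3 and a median of 0.39 (camera adjusted p = 4.66e-05, adjusted p = 0.686 with an estimated correlation).

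By limma, 0 of 25852 probes passed at an adjusted p under 0.05, and the smallest adjusted p was 0.682. At an unadjusted p under 0.05 there were 951 probes, where 1293 would be expected, and as for diet this shortfall is no evidence of no difference. The looser count held 97 probes, 41 higher and 56 lower at time 4, of which 20 had a description. The count ranged from 37 (without control pool 12) to 598 (without control pool 10) when single pools were left out, with 53 without control pool 18, 60 without control pool 7, 187 without control pool 17 and 200 without control pool 3. Leaving out control pool 7 gave 6 probes past the adjusted threshold. Control pools 6 and 18 are both of sampling time 3, and the looser count was 308 without them.

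Of the named probes with higher values at time 4, Hemicentin-1, an extracellular matrix protein, differed most, by 6.87 (SE 0.46), but the time 3 pools measured were control pools 6 and 18 alone, and the difference was 3.54 with poor spots kept. That is below the 4.02 of Zinc metalloproteinase nas-7 with poor spots kept. Zinc metalloproteinase nas-7 differed by 4.02 (SE 0.84) over all 7 pools, but was above background in 1 of the 4 time 3 pools. Serine protease nudel differed by 5.25 (SE 0.77), Elongation of very long chain fatty acids protein AAEL008004 by 4.71, E3 ubiquitin-protein ligase RNF216 by 2.91 (SE 0.31) and Cytoplasmic tRNA 2-thiolation protein 1 by 1.84 (SE 0.34), each on 2 to 4 pools, and with poor spots kept these were 2.83, 2.24, 1.45 and 1.06. The elongation protein was measured on 1 pool per time, so its own spread is unknown, and nudel was measured on 1 pool of time 4 and the thiolation protein on 1 of time 3. With poor spots removed, no time 3 pool other than control pools 6 and 18 measured nudel, the elongation protein, RNF216 or the thiolation protein. Cuticle protein CP14.6 differed by 1.61 (SE 0.39, and by 0.61 with poor spots kept). Adenylyl-sulfate kinase differed by 0.59 (SE 0.17), Contactin-associated protein-like 2 by 0.93 (SE 0.27) and a protein described as 2A060605 by 1.09 (SE 0.31, and by 0.71 without control pools 6 and 18). Hemicentin-1 and Cuticle protein CP14.6 were saturated on 2 time 4 arrays each and the elongation protein on 1, so these sizes are uncertain. An undescribed probe, number 20953, differed by 2.99 (SE 0.44).

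Of the named probes with lower values at time 4, Glucose-6-phosphate 1-dehydrogenase, the first enzyme of the pentose phosphate pathway, differed by -1.21 (SE 0.30), the ESSS subunit of respiratory complex I by -0.74 (SE 0.19), Sulfotransferase 1C4 by -0.96 (SE 0.27, and by -0.62 without control pools 6 and 18) and Protein CutA by -0.61 (SE 0.17). A LIM domain protein differed by -1.23 (SE 0.29), Major royal jelly protein 3 by -1.85 (SE 0.45), Collagen alpha-1(XI) chain by -2.47 (SE 0.36) and Uncharacterized protein sll1483 by -2.95 (SE 0.40). These last 4 were measured on 3 to 5 pools, and with poor spots kept they were -0.81, -1.04, -1.07 and -1.30. The LIM domain protein was saturated on 1 time 3 array and sll1483 on 2, and sll1483 and Collagen alpha-1(XI) chain were measured on 1 pool of time 4. No time 3 pool other than control pools 6 and 18 measured these 2. Without control pools 6 and 18, 12 of the 20 named differences for time could be estimated, all 12 with the same sign. The rest could not be estimated without these pools. Because the 20 probes were chosen by their small p on the same arrays, the kept signs were likely beforehand and are no support. With poor spots kept, Myosin heavy chain, muscle was -1.09 and Troponin I was -0.63, and with 1 value per name they were -0.76 and -0.94. By the latter, Hemicentin-1 was 2.70 and the elongation protein 0.59. An undescribed probe, number 6508, differed by -1.81 (SE 0.31).

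By camera, 8 of the 18 lists tested passed for time, and 0 passed with an estimated correlation, by fry or by exact permutation, where the smallest p that 35 splits allow is 0.0286. After adjustment, a list could pass by permutation only if most of the 18 lists reached that p. In no list did a probe pass, adjusted over all probes or adjusted over the list alone. The muscle list, given above, had list means of -0.68 ± 0.60 (SD, n = 3) against 0.00 ± 0.55 (SD, n = 4), exact permutation p = 0.171. Within slides 1 and 4, the slides with both times among control pools, the muscle means differed by -0.40 and -1.44, and the time 3 pool of slide 4 was control pool 6. No slide 4 difference for time is therefore free of control pool 6, and the values with slide as a block draw on slide 4 too. The cathepsin and lysosomal list had list means of 0.17 ± 0.26 (SD, n = 3) against -0.31 ± 0.18 (SD, n = 4), exact permutation p = 0.0571. Its members with the smallest p were membrane proteins of lysosomes and not proteases: Lamp at 0.42 (SE 0.16) and Lysosome membrane protein 2 at 0.66 (SE 0.27, and at 0.36 without control pools 6 and 18). Without control pools 6 and 18 its median was 0.25 (camera adjusted p = 2.39e-05), and within slides 1 and 4 its means differed by 0.56 and 0.37.

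The list of other digestive peptidases rose, with a median of 0.24 over 114 probes (camera adjusted p = 0.00591, adjusted p = 0.686 with an estimated correlation), and a call lost without control pool 10 (median 0.26) or 17 (0.12), where single pools moved it from 0.12 to 0.35. Putative aminopeptidase W07G4.4 differed by 0.48 (SE 0.17), and within slides 1 and 4 the list means differed by 0.88 and 0.35. The protease inhibitor list fell, with a median of -0.41 (camera adjusted p = 0.00653, adjusted p = 0.686 with an estimated correlation). The call was lost without control pool 6 (median -0.30) or 18 (-0.17), the median was -0.59 without control pool 10, and without both 6 and 18 it was 0.21. Of its members, a Kunitz-type protein of the KU family differed by 0.66 (SE 0.23), but by -0.215 in 1 of 23 alternatives. Kunitz/BPTI-like toxin differed by -1.96 (SE 0.66, on 1 pool of time 4, saturated on 2 time 3 arrays, by -0.84 with poor spots kept and by -1.27 without control pools 6 and 18). With slide as a block the median was -0.15 (camera adjusted p = 0.092), and within slides 1 and 4 the list means differed by 0.58 and -1.14.

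The cell cycle and DNA replication list rose, with 103 of 122 probes higher and a median of 0.40 (camera adjusted p = 9.49e-06, adjusted p = 0.686 with an estimated correlation). Cell division cycle 2-like protein kinase CG7597 differed by 0.51 (SE 0.20) and a chromosome segregation ATPase by -1.07 (SE 0.44). Without control pools 6 and 18 the latter was -0.58 and the list median was -0.05 (camera adjusted p = 0.22). Single pools moved the median from 0.20 to 0.53, and within slides 1 and 4 the list means differed by -0.14 and 1.15. The proteasome and ubiquitin list rose, with a median of 0.06 (camera adjusted p = 0.0487, adjusted p = 0.686 with an estimated correlation), and Ubiquitin carboxyl-terminal hydrolase 34 differed by 0.61 (SE 0.22). Its call was lost without control pool 3 (median 0.08), 6 (0.05), 7 (0.05) or 18 (0.07), and its median was -0.02 without both 6 and 18. With slide as a block the median was 0.08 (camera adjusted p = 0.102), and within slides 1 and 4 the list means differed by -0.09 and 0.39.

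The oxidative phosphorylation list fell, with 139 of 181 probes lower and a median of -0.21 (camera adjusted p = 3.86e-05, adjusted p = 0.686 with an estimated correlation). ATP synthase subunit gamma differed by -0.65 (SE 0.21, saturated on 1 time 3 array) and Cytochrome b-c1 complex subunit 8 by -0.71 (SE 0.22, and by -0.35 with poor spots kept). With poor spots removed, no time 3 pool other than control pools 6 and 18 measured the latter. Without control pools 6 and 18 the median was -0.01 (camera adjusted p = 0.845). Leaving out single pools gave -0.29 to -0.13, and within slides 1 and 4 the list means differed by 0.07 and -0.55. The host blood list fell, with 11 of 12 probes lower and a median of -0.68 (camera adjusted p = 0.00204, adjusted p = 0.686 with an estimated correlation). All 8 probes of its 3 immunoglobulin-domain names, which arthropods also make, were lower, as were the 2 probes of Serotransferrin (-0.62 and -0.38) and 1 of 2 probes of Minor histocompatibility antigen H13. Whether any probe of this list reads salmon RNA was not tested, so its fall is no measure of host blood. Leucine-rich repeats and immunoglobulin-like domains protein 1 differed by -1.33 (SE 0.43, and by -2.06 with slide as a block) and an I-set domain protein by -1.11 (SE 0.53, and by -0.34 without control pools 6 and 18). Without control pools 6 and 18, which had list means of 0.79 and 0.57, the median was -0.08 (camera adjusted p = 0.37). Leaving out single pools gave -1.08 to -0.52, and within slides 1 and 4 the list means differed by -0.34 and -1.71.

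The other 10 lists tested did not pass for time (camera adjusted p from 0.0895 to 0.945). The digestive serine protease list had a median of 0.31 and passed as higher without control pool 6 (median 0.25) or 18 (0.21) or without both (0.38). The median was 0.13 without control pool 3, where it did not pass. Its member Trypsin-2, a digestive serine protease, was saturated in the sample channel on all 3 time 4 arrays. Its log2 difference was 2.93 (SE 0.92) from the 2 of 4 time 3 pools measured, 1.5 without control pool 17, 4.37 without control pool 10 and 1.86 with poor spots kept, so its size is uncertain. The median was 0.06 for heat shock and chaperones, with DnaJ protein homolog 1 at -1.02 (SE 0.35) and DnaJ homolog subfamily B member 6-A at 0.53 (SE 0.20). It was -0.05 for antioxidant defence, with Thioredoxin-2 at -0.62 (SE 0.21) and Thioredoxin domain-containing protein 9 at -0.61 (SE 0.27), and -0.03 for xenobiotic metabolism and transport, with Carbohydrate sulfotransferase 1 at -1.32 (SE 0.44). It was 0.09 for sperm and testis, with Nuclear autoantigenic sperm protein at 1.22 (SE 0.58) and Spermatogenesis-associated protein 5-like protein 1 at -0.50 (SE 0.22), and -0.17 for cuticle and chitin, with a chitin-binding protein at -0.87 (SE 0.34), and the cuticle list passed as lower without control pool 3 (median -0.51) or 6 (-0.35). The cuticle median ranged from -0.51 to 0.17 without single pools, and within slides 1 and 4 the cuticle list means differed by -0.47 and 0.26. The median was -0.17 for nervous system, with Extended synaptotagmin-3 at 3.77 (SE 1.49, 2 of 7 probes higher) and Sodium- and chloride-dependent GABA transporter 1 at 1.39 (SE 0.57), and this list passed as lower without control pool 10 (median -0.31) or 17 (-0.31) but as higher without control pools 6 and 18 (median 0.14, camera adjusted p = 0.00204). It was 0.00 for cytosolic ribosomal proteins, with 60S ribosomal protein L7a at 0.76 (SE 0.28) and 60S ribosomal protein L44 at 2.80 (SE 1.21, saturated on 2 time 4 arrays, and at 1.75 without control pool 17). It was 0.06 for iron and haem, with an animal haem peroxidase at 2.83 (SE 1.52, 2 of 6 probes higher) and the FhaB family exoprotein at -1.06 (SE 0.40, saturated on 2 time 3 arrays, and at -0.05 with poor spots kept), and 0.13 for lipid storage and transport, with 3-ketoacyl-CoA reductase at 1.76 (SE 0.82). Several of these genes moved without control pools 6 and 18: Extended synaptotagmin-3 was then 1.23, Sodium- and chloride-dependent GABA transporter 1 0.51, the animal haem peroxidase 0.20, Nuclear autoantigenic sperm protein 0.30, 3-ketoacyl-CoA reductase 0.56, Thioredoxin domain-containing protein 9 -0.24, Spermatogenesis-associated protein 5-like protein 1 -0.28, the chitin-binding protein -0.44 and the FhaB family exoprotein -0.58. DnaJ protein homolog 1 was -1.70, Carbohydrate sulfotransferase 1 was -2.14 and L7a was 1.22 with slide as a block. Carbohydrate sulfotransferase 1, Extended synaptotagmin-3 and Nuclear autoantigenic sperm protein entered their lists by parts of their names alone. The yolk and eggshell list was not tested and had a median of -0.33 and a mean of 0.01.

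**Figure D3:**
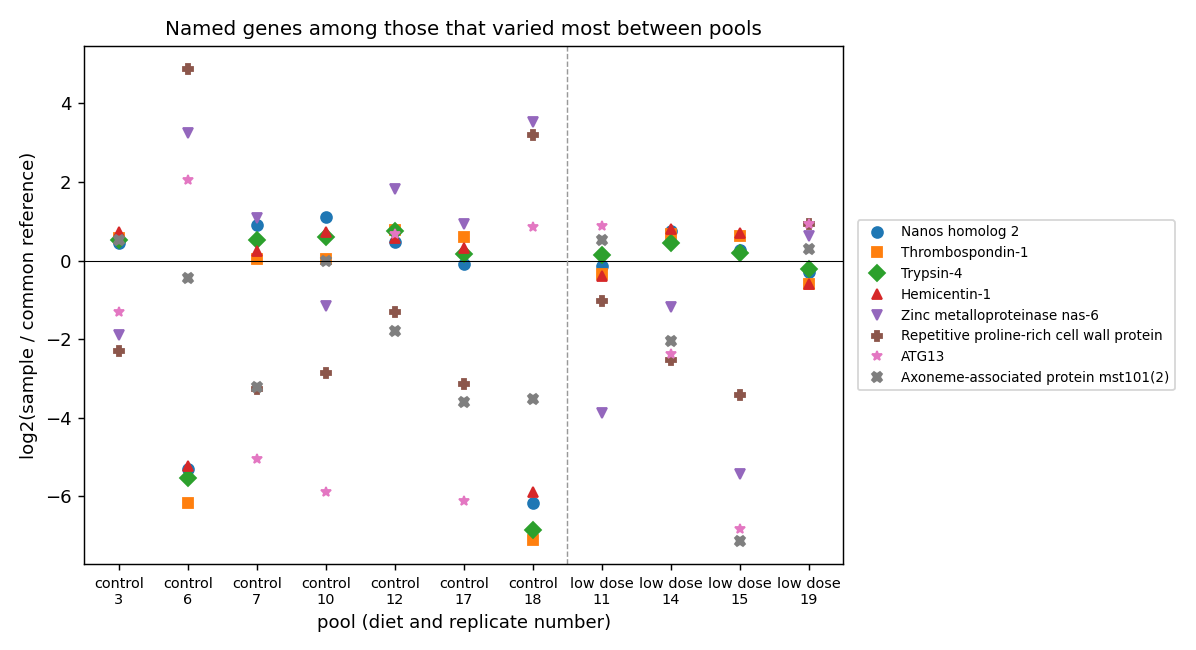
Log2 ratio of sample over reference (vertical axis) of 8 named genes among those with the largest SD between pools, in each control diet pool (left) and each low dose pool (right). Nanos homolog 2, Thrombospondin-1, Trypsin-4 and Hemicentin-1 lie at -5.22 or lower in control pools 6 and 18, and ATG13 and Axoneme-associated protein mst101(2) lie at -6.82 and -7.13 in low dose pool 15.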

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

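The tests of the 3 patterns weighed here were chosen after the patterns were seen. Of 194 groups of 4 to 10 pools examined for a single pool far from the others, 15 had one, and chance gives about 1 in 20.

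Low dose pool 15 stood apart from the other 3 low dose pools in 7 of the results named here. Its list means were -1.74 for protease inhibitors (others -0.33 to -0.09), -1.42 for yolk and eggshell (others -0.28 to -0.12) and 0.09 for lipid storage and transport (others -0.05 to -0.04). Its log2 ratios were -3.48 for a trypsin-like serine protease (others -0.50 to 0.01), -5.23 for Papilin (others -1 to -0.13) and -6.42 for the FhaB family exoprotein (others -0.15 to 0.98). In addition, undescribed probe number 12687 was at 0.74 (others -0.36 to -0.22).

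For the protease inhibitors of pool 15, the tables argue against an effect of the slide, since the other array of its slide lay 1.41 higher. A failed hybridisation was tested only weakly, by 10 positive control sequences. On this array their log2 ratios correlated at 0.984 with the mean of the other arrays, the lowest of the 11 arrays (0.984 to 0.999). Their slope of 0.957 and their mean of -0.56 were the lowest too. These ratios ran from -3.5 to 1.66, so a high r was likely on any array that hybridised. It argues against a gross failure only, and the quality of the sample RNA was not tested. The low dose diet alone would move the other low dose pools too, and the lowest of these was -0.33, inside the range of control pools (-0.64 to 0.89). A difference between the few lice of this pool stays open and was not tested.

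Control pools 6 and 18 stood apart from the other control pools in several results. Pool 6 had 1567 saturated probe spots (others 1068 to 1228) and a log2 ratio of 1.74 for Dehydrogenase/reductase SDR family member 1 (others 0.34 to 0.76). Pool 18 had 0.37 for Prolyl 4-hydroxylase subunit alpha-2 (others -2.73 to -1.50), -0.45 for undescribed probe number 12687 (others -1.61 to -1.15) and 1.69 for the transporter NTT73 (others -0.32 to 0.54). Among the 4 pools of sampling time 3, pool 18 had -1.90 for Zinc metalloproteinase nas-7 (others -3.12 to -2.97) and -0.24 for Putative aminopeptidase W07G4.4 (others -0.04 to -0.01). Control pool 3 had -0.34 for Thioredoxin-like protein 4A (others -0.07 to 0.02).

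For the low cell cycle list of pools 6 and 18 (-1.15 and -0.85), the slide is argued against by their slide mates, the nearest of which lay 0.75 higher. A gross failure of hybridisation is argued against by the positive control sequences, with r of 0.987 or more, although the 0.987 of pool 18 was the second lowest of the 11 arrays. With 10 sequences of widely spread ratios a high r was likely beforehand, so a lesser fault or poor sample RNA stays open. A lower share of RNA from females, or from their ovaries, may underlie the low Nanos homolog 2 and Putative vitellogenin receptor, but Vitellogenin-2 was not low, at -0.92 and -0.05 within or above the range of the other pools. This stays open, because the yolk list has 3 names given by similarity and the labels give equal numbers of both sexes in each pool. A lower share of ovary RNA without a lower share of female RNA was not tested. Sampling time 3 was shared by both pools but also by control pools 10 and 17 and low dose pool 19, whose list means were 0.10, -0.05 and -0.10.

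The log2 ratios of the pools of 4 lice, low dose pools 11 and 19, had the smallest spread, with a mean SD of 0.378 against 0.794 (0.50 to 1.06) in the pools of 2. Compressed ratios are argued against by the positive control sequences, whose slope on the other arrays was 0.999 or more, and the low dose diet by the low dose pools of 2 lice, with SDs of 0.687 or more. Averaging over more lice stays open: the exact two-sided permutation p = 0.0182 is the smallest that 55 splits allow, but these pools were singled out by the same SDs, so it only restates the pattern. The ratio of the spreads was 0.48, where averaging of independent lice would give 0.71.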

How the results depend on the processing

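The alternatives fixed beforehand and those chosen after seeing the data (without pools 6 and 18, without these and low dose pool 15, the cell cycle covariate, poor spots kept, matching on whole descriptions and the permutation of list means) were run for both comparisons, except that sampling time as a covariate, sampling time 4 alone, pools of 2 lice alone and leaving out any low dose pool apply to diet only. None of the 1591 values of named genes for diet and 1112 for time passed the adjusted threshold, and 15 and 2 of them changed sign. The alternatives refit the arrays by which these genes were chosen, so a kept sign says little. Of the 630 list values for diet, 555 kept their side of the threshold, 23 lost and 27 gained a call and 25 changed direction with a call on either side; of the 486 for time these were 421, 46, 11 and 8. With lists past no threshold included, the camera direction changed in 112 values for diet and 47 for time. Quantile normalisation of average intensity changes no log ratio and tests nothing, and the series matrix repeats the authors' table. How well probes near background were tested was not measured, and 63.4% to 70.9% of the probes were above it. The cause of the changes below was not tested, unless the alternative itself removes pools or probes.

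For diet, probes past the adjusted threshold (0) were 1 with pools of 2 lice alone and 0 to 1 without single pools (1 without low dose pool 19). The looser count (31) was 60 with no filter, 15 with the filter on all arrays, 13 with the authors' table and with the series matrix, 48 with slide as a fixed block, 81 in sampling time 4 alone, 54 with pools of 2 lice alone, 301 with array weights, 19 with the trended and robust model, 1 with 1 value per name, 205 without pools 6 and 18, 175 without these and low dose pool 15, 211 with the cell cycle covariate, and 22 to 50 without single pools (50 without control pool 18). Lists called (3) were 5 with the authors' table and the series matrix, 6 with pools of 2 lice alone, 6 with array weights, 8 without pools 6 and 18, 7 without these and pool 15, 6 with the covariate, 0 with an estimated correlation, 0 by fry, 0 by exact permutation, and 2 to 5 without single pools (5 without control pool 7).

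For time, probes past the adjusted threshold (0) were 3 with the cell cycle covariate and 0 to 6 without single pools (6 without control pool 7). The looser count (97) was 163 with no filter, 63 with slide as a fixed block, 757 with array weights, 4 with 1 value per name, 308 without pools 6 and 18, 323 with the covariate, and 37 to 598 without single pools (37 without pool 12, 598 without pool 10). Lists called (8) were 5 without pools 6 and 18, 4 with the covariate, 0 with an estimated correlation, 0 by fry, 0 by exact permutation, and 7 to 8 without single pools.

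Medians for diet of lists that changed direction with a call on either side were as follows. The muscle list was 0.42 with slide as a fixed block, 0.17 with sampling time as a covariate, 0.22 in sampling time 4 alone, 0.35 with array weights, 0.24 without pools 6 and 18, 0.27 without these and pool 15, and 0.20 with the cell cycle covariate. The cell cycle list was 0.028 with slide as a block, -0.003 in sampling time 4 alone, -0.07 with array weights, -0.077 without pools 6 and 18, -0.049 without these and pool 15, and -0.033 with its own mean as covariate, which tests nothing for this list. Oxidative phosphorylation was 0.11 with array weights, 0.10 without pools 6 and 18, 0.083 without these and pool 15, and 0.083 with the covariate, and nervous system was 0.14, 0.16, 0.13 and 0.13 in the same order. Host blood was 0.35 with array weights and 0.24 without pools 6 and 18, cuticle and chitin was -0.27 with pools of 2 lice alone, and protease inhibitors were -0.12 without pools 6, 18 and 15, where camera pointed up. For time, without pools 6 and 18, protease inhibitors were 0.21, oxidative phosphorylation -0.011 (camera up), nervous system 0.14, proteasome and ubiquitin -0.015 and cell cycle -0.053, and with the covariate protease inhibitors were 0.12, proteasome and ubiquitin 0.002 and cell cycle 0.002.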

Other observations

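Several of the genes with the largest SD between pools were extreme in control pools 6 and 18 or in low dose pool 15, and others, such as ATG13, varied over most pools. In control pools 6 and 18, Nanos homolog 2, named after a regulator of germ cells, had mean log2 ratios of -5.35 and -6.29 (2 probes), against -0.50 to 0.72 in the other 9 pools. Thrombospondin-1 had -6.17 and -7.11, Tenascin had -5.80 and -5.45, and Hemicentin-1 had -5.22 and -5.89, all 3 named after extracellular matrix proteins, and Trypsin-4 had -5.52 and -6.85. A repetitive proline-rich protein lay the other way, at 4.86 and 3.19, against -3.42 to 0.92 elsewhere. The Putative vitellogenin receptor, which takes up yolk protein into oocytes, had -4.05 and -4.45, against -0.35 to 1.03 elsewhere, while Vitellogenin-2 had -0.92 and -0.05, against -1.88 to -0.43. These genes were chosen after their values were seen.

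In low dose pool 15, Axoneme-associated protein mst101(2), named after a protein of sperm tails, had a log2 ratio of -7.13, against -3.60 to 0.53 in the other pools. ATG13, named after an autophagy protein, had -6.82 in this pool, -6.12 in control pool 17, -5.89 in control pool 10 and -5.06 in control pool 7, and 2.04 in control pool 6. A probe described as a high molecular weight glutenin subunit had -6.31, -5.52, -5.11, -4.63 and 1.94 in the same pools, so these probes may not be separate findings. Whether the ATG13 probe reads an autophagy gene was not checked. Zinc metalloproteinase nas-6, which is also among the genes named for diet, had -5.42 in low dose pool 15 and -3.88 in low dose pool 11, and 3.25 and 3.52 in control pools 6 and 18 (a probe other than the one named for diet).

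Other splits of the arrays, a test planned before the data were examined, gave looser counts and list counts as large as the real ones. For diet, 100 splits into 4 and 7 arrays, the real one included, were drawn from the 330 possible. With 0 probes past the adjusted threshold in the real split, any split gives at least as many (100 of 100, highest other 1580), so that count tests nothing. In the looser count 76 gave at least its 31 probes (highest other 3481), and 94 gave at least its 3 lists (highest other 11), so chance cannot be excluded for either. For time, the 35 splits of the 7 control arrays test nothing at the adjusted threshold for the same reason (35 gave at least 0 probes, highest other 145). In the looser count 18 gave at least 97 probes (highest other 2266), and 12 gave at least 8 lists (highest other 11), so chance cannot be excluded there. The splits with 3481 and 2266 probes put control pools 6, 18 and 3 on the same side, the former with low dose pool 19. Counts so far above the real ones point to a structure of the samples other than diet and time.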
